A study of Gallus gallus with 32 samples.

How the data were processed

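Liver RNA of Arbor Acres broilers, a commercial line of meat chickens, was measured by messenger RNA sequencing in 32 libraries, 8 from each of 4 diets with 0, 1.8, 9 or 18 g/kg of added arginine. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was selected by its poly(A) tail, strand-specific Illumina libraries were built, and paired reads were sequenced on a NovaSeq X Plus. Per the submitters' processing notes, fastp, HISAT2, StringTie and RSEM were used. The notes give neither their versions nor the step each tool served, and they name no genome build.

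The authors deposited 1 table of TPM, the transcript abundance unit, with 25619 genes named by symbol. TPM divides each gene's reads by its transcript length and scales a library to a fixed total, so a value is a share of that library's RNA. The sums ran from 998707 to 999281 per library, so a small part of each library is not in the table. Counts were not used here. The sequencing depth of each library is therefore unknown, and no counting interval or detection limit can be given. Of the 25619 IDs, 25368 matched a symbol of the chicken reference table (assembly GRCg7b), 13 were named through a locus tag and 238 had no match. The table served for names and for membership of the W and Z chromosomes, and no coordinates are given because the authors' build is not stated.

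Libraries were grouped by dose as the labels give it. Nothing in the labels says that the 8 libraries of a diet came from separate animals, so p-values measure the spread between these libraries. The groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Exceptions are the exact permutation tests of list means, which were not planned, and those that the closing section says were chosen after seeing the data. Values were log2(TPM + 1), and the 11339 genes with a mean of at least 1 TPM over the 32 libraries were tested. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow mean expression (eBayes, trend=TRUE). Contrasts were each dose against control, each pair of doses, any difference among the 4 groups (F test), and a linear trend on the dose in g/kg. P-values are 2-sided, were adjusted by the Benjamini-Hochberg method over the tested genes, and genes were called at an adjusted p below 0.05.

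The procedure was tested on simulated data with 200 changed genes among 11339 in the comparison of 9 g/kg with control. It called 12% of genes changed 1.5-fold, 69.5% of genes changed 2-fold and 94% of genes changed 4-fold, with 3, 5 and 15 false calls. Residuals were shuffled separately for each gene, which removed the correlation between genes. These rates and false calls therefore describe independent genes and not the correlated genes of these libraries. The median standard error of a log2 difference was 0.17, and the median 95% interval reached 0.34 to either side.

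There were 32 gene lists. The metabolic and stress lists were arginine, ornithine, polyamine and creatine metabolism, uric acid and purine synthesis, fatty acid synthesis, triglyceride synthesis and lipoprotein export, fatty acid oxidation and ketogenesis, cholesterol synthesis and uptake, bile acid synthesis and sterol clearance, glucose and glycogen metabolism, the growth hormone, insulin and thyroid axis, the ATF4 amino acid response, the unfolded protein response, heat shock, antioxidant and xenobiotic defence, acute phase and inflammation, interferon response, cell cycle, circadian clock, immediate early genes, nuclear OXPHOS subunits and cytosolic ribosomal proteins. Cell type markers covered hepatocytes, T and NK cells, B and plasma cells, macrophages and Kupffer cells, heterophils, erythrocytes, stellate cells and fibroblasts, endothelial cells, cholangiocytes, adipocytes, pancreatic acinar cells and skeletal muscle. Lists were tested against control with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, then with an estimated correlation, and with fry. In 20 simulations with 1 list shifted by 0.5 log2, camera at the preset correlation called that list 20 times and 9.9 unchanged lists per simulation. Calls at the preset correlation alone are thus weak evidence here. Differences of list means between groups were also tested by exact permutation of the 16 libraries, unadjusted unless given as adjusted over the lists of a dose. Pancreatic acinar cells and skeletal muscle had 1 tested gene each and were not tested as lists. Counts of list members refer to tested genes only, which for some lists are a small part. Of 14 listed B and plasma cell symbols 5 were tested, and of 19 heterophil symbols 6.

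Genes were named by rule. For each dose these were the 5 higher and 5 lower genes with the smallest unadjusted p (fewer than 5 were called), members of the lists with the smallest p (up to 4), and a fixed set of 33 genes of arginine and lipid metabolism where tested. Not every gene the rule selects is printed. The trend and F tests contributed their 5 smallest p in each direction. For overlap between doses, unchanged groups were simulated 100 times from within-group residuals with the same control libraries, and the controls were also split by odd and even replicate number.

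Alternatives were a pseudocount of 0.1, a minimum mean of 0.1 TPM, no filter, rescaling by median ratios, the replicate number as a block, library weights with robust eBayes, the mean of W-linked genes or of erythrocyte markers as a covariate, a minimum difference of 1 log2, only the compared groups in the fit, the rank of the dose, and each library left out in turn. Within each group a library was singled out when its gap to the nearest other, over the group's range, exceeded Dixon's 95% critical value. Results were compared with 100 random splits of the same libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.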

Results

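Dietary arginine was added at 4 levels, 0 (control), 1.8, 9 and 18 g/kg, and liver transcripts were measured in 8 libraries per level. Group values are TPM means ± SD (n = 8), and log2 differences on log2(TPM + 1) are given ± SE. The series' title names tissue-specific lipid metabolism in liver and breast muscle. The deposited libraries are liver only, and fewer than the number of liver samples its design text counts. Per library, 10353 to 11678 genes reached 1 TPM and 16069 to 17341 were above 0. Depth is unknown, since only TPM are given. Albumin (ALB) was the most abundant transcript, with a mean of 83013 TPM, and the 10 most abundant genes took 26.7 to 33.7% of a library. Mitochondrially encoded transcripts took 16 to 25.6%, with group medians of 20.3% in control and 21.8, 22.4 and 23.0% at 1.8, 9 and 18 g/kg.

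The first comparison asked how liver transcripts at the lowest added dose, 1.8 g/kg, differ from control. The lists of endothelial and of B and plasma cell markers had higher means at the preset correlation and did not pass with an estimated one (adjusted p = 0.336 for both). JCHAIN, the joining chain of secreted immunoglobulin, stood at 34.1 ± 17.0 TPM against 16.4 ± 7.74 (log2 difference 1.02 ± 0.37), above the control mean in 8 of 8 libraries. LYVE1, a hyaluronan receptor of liver sinusoids, stood at 19.7 ± 5.54 TPM against 12.6 ± 6.02 (0.72 ± 0.24, 8 of 8, and 0.48 without control replicate 7). AGMAT, agmatinase, which hydrolyses agmatine to putrescine, stood at 121 ± 38.9 TPM against 82.2 ± 25.6 (0.55 ± 0.18, 7 of 8). No gene passed the test. With limma, 0 of 11339 genes were called (lowest adjusted p = 1), and 265 genes had an unadjusted p below 0.05. Of these, 164 were higher and 101 lower (61.9% higher, and 51.7% after median-ratio rescaling). Chance alone would give 567 on average, and other random splits of the same libraries had a median of 557.

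The 5 higher genes with the smallest unadjusted p at 1.8 g/kg, none of which passed, were RASGRP3 (0.63 ± 0.16), a guanine nucleotide exchange factor, NAALAD2 (0.78 ± 0.20), GHDC (0.44 ± 0.13), the mitochondrial import chaperone TIMM13 (0.45 ± 0.13) and the methyl-CpG-binding protein MBD2 (0.42 ± 0.12). The 5 lower ones, which did not pass either, were the coagulation factor XIII subunit F13B (-0.41 ± 0.11), the hydroxysteroid dehydrogenase HSD17B11 (-0.74 ± 0.22), the serpin SPIA1 (-0.47 ± 0.15), the serine hydroxymethyltransferase SHMT1 (-0.53 ± 0.17) and plasminogen activator PLAT (-0.34 ± 0.11). SHMT1 stood at 227 ± 50.9 TPM against 324 ± 56.6, below the control mean in 8 of 8 libraries.

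Of the 30 tested lists, 12 were called at 1.8 g/kg at the preset correlation and 0 with an estimated one. Endothelial markers were higher in 15 of 15 members, with a mean of 0.36 ± 0.16 (adjusted p = 2.82e-08, and adjusted p = 0.336 with an estimated correlation). B and plasma cell markers were higher in 5 of 5, with a mean of 0.51 ± 0.23 (adjusted p = 0.00139, and adjusted p = 0.336 with an estimated correlation). Nuclear OXPHOS subunits were higher in 64 of 72 (mean 0.11 ± 0.11) and ribosomal proteins in 64 of 70 (mean 0.08 ± 0.08), both with adjusted p = 1.22e-05, and adjusted p = 0.824 with an estimated correlation. Cell cycle genes (16 of 23 higher, mean 0.32 ± 0.36, adjusted p = 0.00245) and erythrocyte markers (11 of 12 higher, mean 0.22 ± 0.20, adjusted p = 0.0185) had adjusted p = 0.824 with an estimated correlation. Purine and uric acid genes were lower in 12 of 19 (mean -0.12 ± 0.10, adjusted p = 0.00648, and adjusted p = 0.383 with an estimated correlation), SHMT1 and xanthine dehydrogenase XDH (-0.79 ± 0.49, and -0.45 without 1.8 g/kg replicate 5) among them. Interferon response genes were lower in 20 of 23 (mean -0.20 ± 0.41, adjusted p = 0.0114) and immediate early genes in 10 of 14 (mean -0.15 ± 0.22, adjusted p = 0.0185), both with adjusted p = 0.824 with an estimated correlation. Hepatocyte markers were lower in 18 of 21 (mean -0.05 ± 0.08, adjusted p = 0.0237) and antioxidant genes in 15 of 27 (mean -0.13 ± 0.12, adjusted p = 0.0275), both with adjusted p = 0.621 with an estimated correlation. Stellate cell markers were lower in 11 of 17 (mean -0.13 ± 0.22, adjusted p = 0.0359, and adjusted p = 0.824 with an estimated correlation). The exact permutation test of the list mean gave p = 0.0182 for B and plasma cells and p = 0.0904 for endothelium (0.546 and 0.915 adjusted over the lists). Control replicate 7 stood apart in the interferon, ribosomal and endothelial lists, and 1.8 g/kg replicate 4 in the cell cycle and B cell lists. With each of the 16 libraries left out in turn, 2 of the 12 lists were called each time, B and plasma cells and endothelium, and each of the other 10 calls ended at least once. Without control replicate 7 the interferon mean was 0.20 ± 0.32, the ribosomal mean 0.00 ± 0.07, the endothelial mean 0.20 ± 0.12, the OXPHOS mean 0.06 and the immediate early mean -0.04. Without 1.8 g/kg replicate 4 the cell cycle mean was 0.04 and the B cell mean 0.35. The largest moves of the other list means gave 0.08 for erythrocytes (without 1.8 g/kg replicate 1), -0.01 for hepatocytes (1.8 g/kg replicate 3), -0.06 for antioxidant genes (control replicate 2), -0.02 for stellate cells (control replicate 4) and -0.07 for purine genes (control replicate 8).

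At 9 g/kg, the middle dose, AGMAT and MBD2 had higher values and SCD and G6PC lower ones, none passing the test. AGMAT stood at 140 ± 34.2 TPM against 82.2 ± 25.6 (0.78 ± 0.18, adjusted p = 0.432) and MBD2 at 90.3 ± 18.3 against 58.5 ± 10.2 (0.61 ± 0.12, adjusted p = 0.206), each above the control mean in 8 of 8 libraries. SCD, stearoyl-CoA desaturase, which makes monounsaturated fatty acids, stood at 1.87 ± 1.64 TPM against 15.7 ± 17.8 (-1.94 ± 0.80, adjusted p = 0.906), and G6PC, glucose-6-phosphatase, at 336 ± 233 TPM against 710 ± 435 (-1.02 ± 0.42, adjusted p = 0.906). SOCS2, a suppressor of growth hormone signalling, stood at 38.0 ± 16.5 TPM (1.22 ± 0.37 over control, adjusted p = 0.778), above the control mean in 8 of 8. No gene passed. With limma, 0 of 11339 genes were called, the lowest adjusted p was 0.206, and 552 genes had an unadjusted p below 0.05. Of these, 245 were higher and 307 lower (44.4% higher, and 48.9% after rescaling). Chance alone would give 567 on average, and other random splits of the same libraries had a median of 426 (121 to 1632). Without control replicate 7, 910 genes had an unadjusted p below 0.05 and 0 were called.

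**Figure D1:**
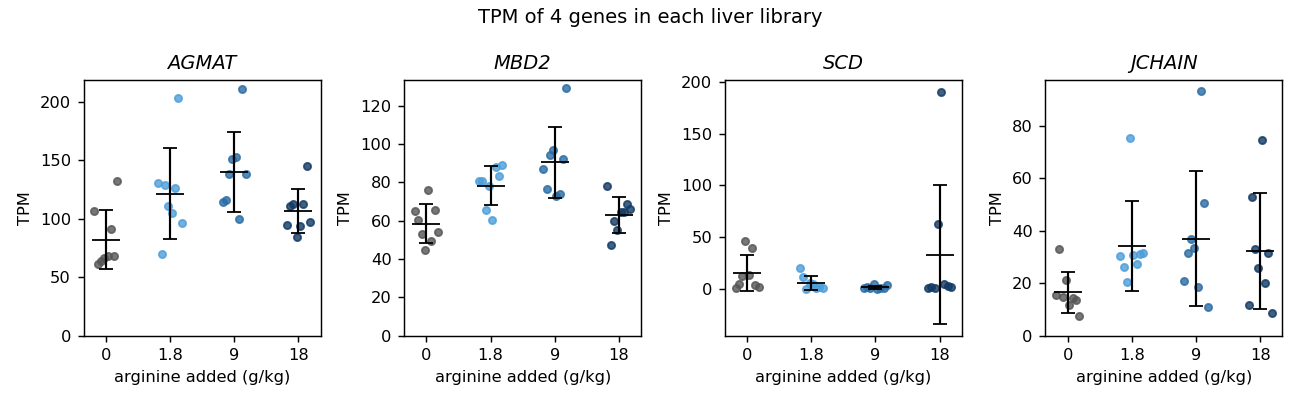
TPM of AGMAT, MBD2, SCD and JCHAIN (vertical axes) in each of the 32 liver libraries against added arginine in g/kg; points are libraries, and bars give the mean ± SD of the 8 libraries of a dose. AGMAT means were 82.2, 121, 140 and 107 TPM, and the SCD mean at 18 g/kg includes replicate 5 at 191 TPM.

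Among the 5 higher genes with the smallest unadjusted p at 9 g/kg, none passing, were MBD2, AGMAT, the B cell coactivator POU2AF1 (0.64 ± 0.16) and TUB4A (0.73 ± 0.19). The 5 lower were the tetraspanin TSPAN15L (-0.52 ± 0.12, adjusted p = 0.432), TCTEX1D2 (-0.65 ± 0.15), PPIL6 (-1.2 ± 0.29), NCOA7 (-0.84 ± 0.22) and the interleukin-7 receptor IL7R (-0.85 ± 0.23). Of these 2 sets, POU2AF1 and PPIL6 had low values. POU2AF1 stood at 1.62 ± 0.66 TPM against 0.68 ± 0.45 in control, and PPIL6 at 0.305 ± 0.343 TPM against 2.325 ± 1.80. The reference table places MBD2 on the W chromosome, which in birds only females carry. Yet MBD2 ran from 44.6 to 129 TPM in the 20 libraries where the W-linked transcript HINTW was listed at 0, so which gene copies the MBD2 row measures is not known. With W-linked expression as a covariate MBD2 differed by 0.65 log2 (adjusted p = 0.0798, within a range of 0.0228 to 0.954 over the alternatives). IL7R lies on the Z chromosome in the same table. When adjusted over the list alone, 5 genes had an adjusted p below 0.05 at 9 g/kg, against 0 over all genes tested. They were AGMAT in the arginine list (0.0029), SOCS2 in the growth hormone list (0.0351), IL7R in the T cell list (0.0092), and POU2AF1 and JCHAIN in the B cell list, where the lowest was 0.0013. At 1.8 and at 18 g/kg the number adjusted over the list alone was 0.

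At 9 g/kg, 7 of 30 lists were called at the preset correlation and 0 with an estimated one. Endothelial markers were higher in 15 of 15 (mean 0.38 ± 0.16, adjusted p = 1.04e-07, and adjusted p = 0.406 with an estimated correlation), STAB1 (0.54 ± 0.21) and LYVE1 (0.61 ± 0.24, and 0.36 without control replicate 7) among them. B and plasma cell markers were higher in 5 of 5 (mean 0.58 ± 0.23, adjusted p = 0.000158, and adjusted p = 0.238 with an estimated correlation). Erythrocyte markers were higher in 9 of 12 (mean 0.27 ± 0.20, adjusted p = 0.0181), macrophage markers in 17 of 17 (mean 0.40 ± 0.44, adjusted p = 0.0239) and heterophil markers in 6 of 6 (mean 0.59 ± 0.55, adjusted p = 0.0431), all 3 with adjusted p = 0.899 with an estimated correlation. Interferon genes were lower in 22 of 23, such as PARP9 (-0.57 ± 0.26) and the helicase DDX60 (-1.09 ± 0.68; -0.34 and -0.64 without control replicate 7), with a list mean of -0.39 ± 0.41 (adjusted p = 0.00379, and adjusted p = 0.899 with an estimated correlation). Cholesterol synthesis and uptake genes were lower in 17 of 19 (mean -0.26 ± 0.34, adjusted p = 0.044, and adjusted p = 0.899 with an estimated correlation). By exact permutation the list means gave p = 0.0124 for B and plasma cells and p = 0.0446 for endothelium (0.372 and 0.669 adjusted over the lists, and 0.0895 unadjusted for endothelium without control replicate 7). Control replicate 7 and, among heterophil markers, 9 g/kg replicate 4 stood apart. With each of the 16 libraries left out in turn, 2 of the 7 lists were called each time, B and plasma cells (0.44 to 0.67) and endothelium, and each of the other 5 calls ended at least once. Without control replicate 7 the interferon mean was 0.01 ± 0.32, the endothelial mean 0.23 ± 0.12 and the cholesterol mean -0.14 ± 0.35. Without 9 g/kg replicate 4 the heterophil mean was 0.09. The macrophage mean was 0.19 without control replicate 1 and 0.62 without control replicate 3, and the erythrocyte mean ran from 0.21 to 0.38.

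Purine genes had higher values at 9 g/kg in 13 of 19 members (mean 0.16 ± 0.10, adjusted p = 0.0523, and adjusted p = 0.899 with an estimated correlation). The list was called at the preset correlation without control replicate 5, 7 or 8 or 9 g/kg replicate 4 or 8 (lowest adjusted p = 0.0128). Among the higher members were ADSL, adenylosuccinate lyase (0.81 ± 0.31), and ATIC, which closes the purine ring (0.62 ± 0.30). In the bile acid and sterol list the sterol exporters ABCG5 (0.72 ± 0.26, 8 of 8 libraries above the control mean) and ABCG8 (0.95 ± 0.32, 7 of 8) had higher values. In the triglyceride list MOGAT1, a monoacylglycerol acyltransferase, was higher (1.15 ± 0.50), while APOC3 (-0.38 ± 0.14) and TM6SF2 (-0.48 ± 0.21), which acts in lipoprotein secretion, were lower. None of these passed the test over all genes.

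At 18 g/kg, the highest dose, the nuclear OXPHOS and cell cycle lists had higher means than control at the preset correlation, and neither passed with an estimated one (adjusted p = 0.607 for both). The mitochondrial transcript MT-ND4L was higher by 0.34 ± 0.10, and the nuclear subunits COX8A and NDUFC2 stood at 147 ± 26.9 and 161 ± 13.8 TPM against 114 ± 30.8 and 130 ± 20.7, each above the control mean in 8 of 8 libraries. The proliferation markers NUSAP1 and MKI67 differed by 0.83 ± 0.39 and 0.68 ± 0.37, and by 0.54 and 0.41 without 18 g/kg replicate 5. AGMAT stood at 107 ± 18.9 TPM (0.41 ± 0.18, 8 of 8). No gene passed. With limma, 0 of 11339 genes were called (lowest adjusted p = 1), and 277 had an unadjusted p below 0.05, 188 higher and 89 lower. The share of higher genes among those with such a p was 67.9%, and 45.9% after rescaling, so that balance turns with the scaling. Chance alone would give 567 on average, and other random splits of the same libraries had a median of 458. Without control replicate 3 the unadjusted number was 441.

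Besides MT-ND4L, the higher genes with the smallest unadjusted p at 18 g/kg were GATC (0.43 ± 0.12), a subunit of the mitochondrial glutamyl-tRNA amidotransferase, the DNA methyltransferase DNMT3A (0.43 ± 0.13), the complement regulator CD55 (0.55 ± 0.16) and the transcription factor NFIC (0.40 ± 0.12). The lower ones were the metalloproteinase MMP24 (-0.38 ± 0.11), the semaphorin SEMA4D (-0.51 ± 0.17), TCTA (-0.66 ± 0.22), TMEM132A (-0.32 ± 0.12) and the glucosyltransferase POGLUT1 (-0.42 ± 0.15). None of these 10 genes passed.

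At 18 g/kg, 11 of 30 lists were called at the preset correlation and 0 with an estimated one. Nuclear OXPHOS subunits were higher in 69 of 72 (mean 0.16 ± 0.11, adjusted p = 4.76e-10), cell cycle genes in 23 of 23 (mean 0.52 ± 0.36, adjusted p = 6.57e-08) and endothelial markers in 14 of 15 (mean 0.27 ± 0.16, adjusted p = 8.93e-05). Interferon genes were lower in 21 of 23 (mean -0.44 ± 0.41, adjusted p = 2.19e-06). All 4 of these lists had adjusted p = 0.607 with an estimated correlation. Unfolded protein response genes were lower in 17 of 19 (mean -0.15 ± 0.23, adjusted p = 0.00398), while macrophage markers were higher in 16 of 17 (mean 0.45 ± 0.44, adjusted p = 0.00525) and T and NK cell markers in 10 of 13 (mean 0.23 ± 0.20, adjusted p = 0.0152). These 3 lists had adjusted p = 0.69 with an estimated correlation. B and plasma cell markers were higher in 5 of 5 (mean 0.37 ± 0.23), and growth hormone and insulin axis genes (13 of 16, mean -0.17 ± 0.14), clock genes (10 of 14, mean -0.12 ± 0.10) and hepatocyte markers (15 of 21, mean -0.06 ± 0.08) were lower. Each of these 4 lists had adjusted p = 0.0229, and adjusted p = 0.607 with an estimated correlation. By exact permutation the list means gave p = 0.116 for B and plasma cells, p = 0.16 for endothelium, p = 0.186 for cell cycle and p = 0.198 for nuclear OXPHOS, all 0.978 adjusted over the lists. With each of the 16 libraries left out in turn, 2 of the 11 lists were called each time, nuclear OXPHOS (0.11 to 0.22) and cell cycle, and each of the other 9 calls ended at least once. Without 18 g/kg replicate 5 the cell cycle mean was 0.30. Without control replicate 7 the interferon mean was -0.04 ± 0.32, the endothelial mean 0.11 ± 0.12 and the unfolded protein mean -0.02. The other list means ran from 0.25 to 0.69 for macrophages, 0.15 to 0.32 for T and NK cells, 0.26 to 0.49 for B and plasma cells, -0.23 to -0.09 for the growth hormone axis, -0.18 to -0.06 for clock genes and -0.11 to -0.04 for hepatocytes.

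**Figure D2:**
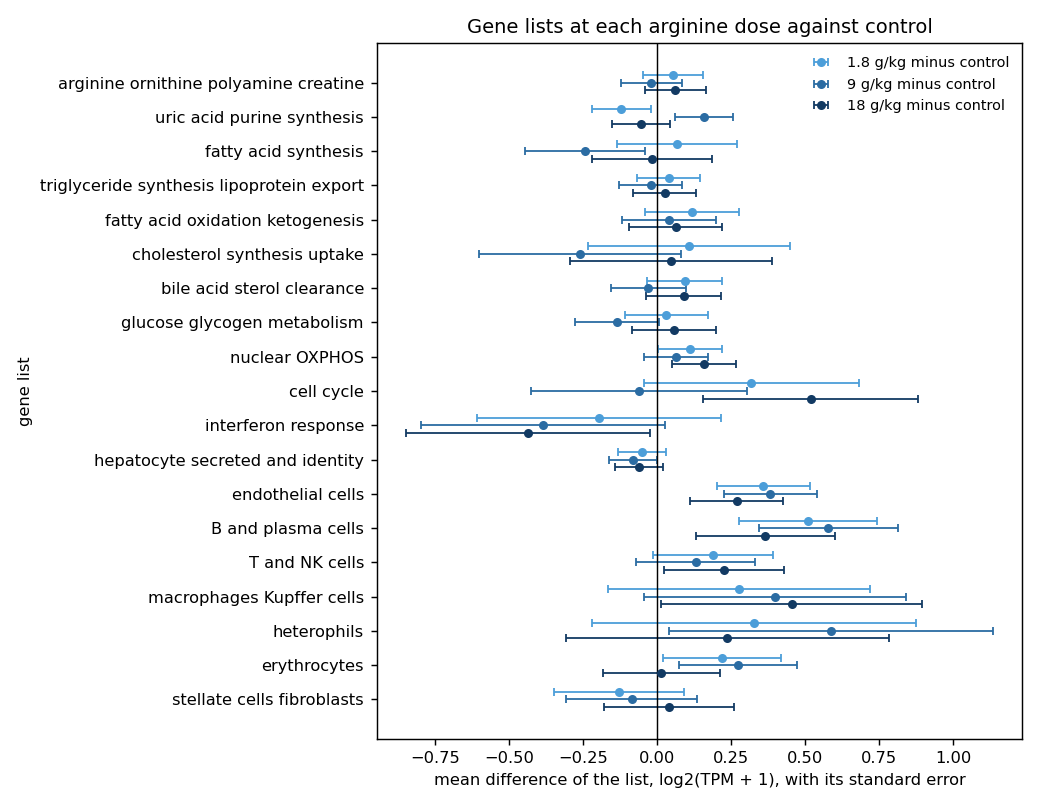
Mean log2 difference from control (horizontal axis, log2(TPM + 1) units) of 19 gene lists at 1.8, 9 and 18 g/kg of added arginine; bars give the standard error of the list mean. Endothelial and B and plasma cell markers lie above 0 at each dose and interferon response genes below it, and 0 lists were called with an estimated correlation.

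**Figure D3:**
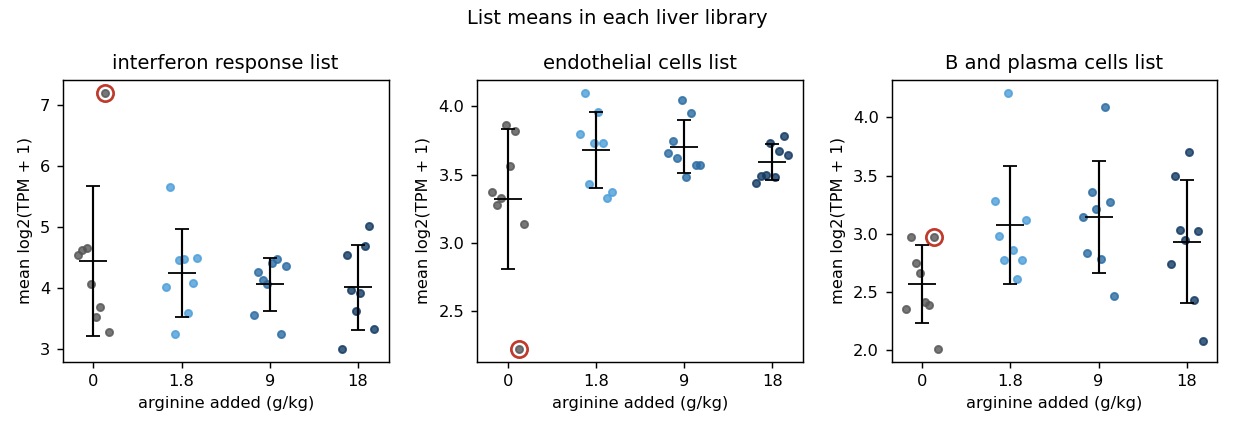
Mean log2(TPM + 1) of the interferon response, endothelial and B and plasma cell lists (vertical axes) in each of the 32 liver libraries against added arginine in g/kg; points are libraries, bars give the mean ± SD of the 8 libraries of a dose, and the ring marks control replicate 7. That library had 7.21 for interferon response and 2.23 for endothelium, apart from the other 7 controls.

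Across doses, genes that handle arginine directly gave differences with wide intervals, and none passed. ASS1, argininosuccinate synthase, differed by 0.04, -0.02 and 0.34 (SE 0.41) at 1.8, 9 and 18 g/kg. Its difference at 18 g/kg was 0.14 without 18 g/kg replicate 2 and 0.53 without control replicate 3. Argininosuccinate lyase ASL differed by 0.21, 0.10 and 0.59 (SE 0.29), GATM, which makes the creatine precursor from arginine, by 0.83, 0.49 and 0.42 (SE 0.61; 0.41, 0.07 and 0.00 without control replicate 1), and ornithine decarboxylase ODC by -0.20, -0.21 and 0.11 (SE 0.27). Ornithine aminotransferase OAT differed by -0.44, 0.21 and 0.06 (SE 0.33), and the cationic amino acid transporter SLC7A2 by -0.11, -0.41 and -0.16 (SE 0.29). DDAH1, which degrades methylated arginine, differed by -0.49, -0.53 and -0.36 (SE 0.25). ARG2, CPS1 and OTC were too low to test, with means of 0.451, 0.569 and 0.00188 TPM, and OTC was listed at 0 in 31 of 32 libraries. Of the fixed set, 30 genes were tested, and those with an unadjusted p below 0.05 were SCD at 9 g/kg and ASL at 18 g/kg. None passed (lowest adjusted p = 0.906). The arginine list was not called, with means of 0.05, -0.02 and 0.06 (SE 0.10; adjusted p = 0.663, 0.963 and 0.427).

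Among lipogenic genes, SCD had group means of 15.7, 5.88, 1.87 and 33.4 TPM, the last with an SD of 66.9, since 18 g/kg replicate 5 reached 191 TPM. Malic enzyme ME1 had means of 30.2, 41.0, 11.7 and 22.9 TPM (0.37, -0.97 and -0.13, SE 0.49), and the elongase ELOVL6 279, 189, 146 and 189 TPM (-0.37, -0.75 and -0.41, SE 0.38; -0.73, -1.11 and -0.77 without control replicate 7). Fatty acid synthase FASN (-0.26, -0.15, -0.10, SE 0.44), ACACA (0.02, -0.05, -0.02, SE 0.39) and ACLY (-0.15, -0.14, -0.22, SE 0.23) differed by less than their standard errors, and ACACA was -0.25, -0.32 and -0.29 without control replicate 1. The regulators SREBF1 (0.33, 0.19, 0.03, SE 0.24), MLXIPL (-0.02, 0.05, 0.07, SE 0.15), THRSP (1.06, 0.39, 0.04, SE 0.71; 0.65 and -0.03 at 1.8 and 9 g/kg without control replicate 7), PPARG (-0.25, 0.01, 0.00, SE 0.20) and PPARA (-0.03, -0.01, -0.04, SE 0.25) did not pass either. In fatty acid oxidation, CPT1A differed by 0.26, -0.13 and -0.23 (SE 0.64), and by 0.27 at 9 g/kg without 9 g/kg replicate 8. No gene of lipid transport and storage passed, with differences for LPL (0.25, -0.03, 0.06, SE 0.37), APOB (0.07, -0.11, 0.02, SE 0.19; -0.07, -0.25 and -0.12 without control replicate 7), MTTP (0.10, -0.17, -0.09, SE 0.14), PLIN2 (-0.13, 0.13, 0.09, SE 0.52; -0.14 at 18 g/kg without 18 g/kg replicate 7) and FABP1 (0.72, -0.12, 0.49, SE 0.42). APOA1, the most abundant apolipoprotein, differed by -0.19, -0.41 and -0.16 (SE 0.21). INSIG1 (-0.20, -0.31, -0.17, SE 0.29) stands for sterol control, PCK1 (0.36, -1.82, -0.31, SE 1.35) for gluconeogenesis, ASNS (-0.16, -0.84, -0.30, SE 0.47) for the amino acid response and IGF1 (0.19, 0.21, 0.00, SE 0.33; -0.14, -0.11 and -0.33 without control replicate 1, and 0.45 at 9 g/kg without 9 g/kg replicate 1) for growth.

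As lists, with all 32 libraries, lipid genes were not called at any dose apart from cholesterol synthesis at 9 g/kg. That list had adjusted p = 0.044 at the preset correlation, and adjusted p = 0.899 with an estimated one. At 1.8, 9 and 18 g/kg, fatty acid synthesis had means of 0.07, -0.24 and -0.02 (adjusted p = 0.777, 0.185 and 0.91), and triglyceride synthesis and export 0.04, -0.02 and 0.03 (0.661, 0.369 and 0.924). Fatty acid oxidation and ketogenesis had means of 0.12, 0.04 and 0.06 (adjusted p = 0.119, 0.369 and 0.3), and bile acid and sterol clearance 0.09, -0.03 and 0.09 (0.995, 0.63 and 0.877). Cholesterol synthesis had means of 0.11 and 0.05 at 1.8 and 18 g/kg (adjusted p = 0.663 and 0.974). Glucose and glycogen metabolism had means of 0.03, -0.14 and 0.06 (adjusted p = 0.714, 0.683 and 0.353). Within it LDHA was lower at 1.8 g/kg (-0.46 ± 0.19), and PFKFB1 (0.45 ± 0.17) and PYGL (0.31 ± 0.13) were higher at 18 g/kg, none passing. The ATF4 amino acid response had means of 0.05, 0.02 and 0.03 (adjusted p = 0.559, 0.523 and 0.974), heat shock 0.04, 0.15 and -0.14 (0.798, 0.185 and 0.0638), and acute phase genes 0.07, -0.06 and 0.01 (0.714, 0.594 and 0.496). Cholangiocyte markers had means of -0.12, -0.05 and 0.03 (adjusted p = 0.192, 0.683 and 0.877) and adipocyte markers 0.05, -0.17 and 0.27 (0.559, 0.523 and 0.236). With 1 library left out, some of these lists were called at the preset correlation. They were fatty acid oxidation at 1.8 g/kg (4 of 16 libraries, with a mean of 0.20 without control replicate 1) and 18 g/kg (0.14 without control replicate 1), fatty acid synthesis at 9 g/kg (-0.28 without 9 g/kg replicate 8), and cholesterol synthesis at 1.8 g/kg (0.29 without 1.8 g/kg replicate 3). Acute phase genes at 1.8 g/kg and heat shock at 9 and 18 g/kg were the others. Acute phase was called with a mean of 0.29 without control replicate 7, and with a mean of only -4e-04 without 1.8 g/kg replicate 8 (camera adjusted p = 0.032). Heat shock at 9 g/kg had 0.27 without control replicate 7 and 0.22 without 9 g/kg replicate 6. At 18 g/kg it was called without control replicate 2, 5, 6 (-0.24) or 8, or without 18 g/kg replicate 1, 2 or 6. With all libraries and an estimated correlation, these lists had adjusted p from 0.824 to 0.947 at these doses. AMY1A stood at 72.4 ± 21.7, 74.9 ± 11.8, 72.0 ± 12.8 and 72.5 ± 19.97 TPM in control and at the 3 doses. Of 17 measured genes of the pancreatic acinar list it was the only 1 with a mean of at least 1 TPM, so it does not by itself mark pancreatic tissue. The muscle actin ACTA1 stood at 1.31 ± 0.93, 1.37 ± 0.83, 2.51 ± 2.34 and 5.95 ± 7.65 TPM. Mean, median and test direction differed in sign for 6 lists at 1.8 g/kg, 3 at 9 g/kg and 5 at 18 g/kg, all uncalled (lowest adjusted p = 0.559, 0.63 and 0.496). These were the triglyceride, glucose, growth hormone, ATF4, acute phase and clock lists at 1.8 g/kg, the arginine, bile acid and growth hormone lists at 9 g/kg, and the fatty acid synthesis, triglyceride, antioxidant, acute phase and stellate lists at 18 g/kg.

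Direct comparisons of the doses asked whether responses differ between them. Between 18 and 9 g/kg the 5 lower and 5 higher genes with the smallest unadjusted p did not pass. PER3, a clock gene, stood at 3.71 ± 1.49 TPM at 9 g/kg and 1.45 ± 0.83 at 18 g/kg (-0.93), SOCS2 at 38.0 ± 16.5 and 14.0 ± 6.40 (-1.40), UPP2, uridine phosphorylase, at 33.4 ± 26.4 and 4.83 ± 3.53 (-2.29), MBD2 at 90.3 ± 18.3 and 62.9 ± 9.28 (-0.51), and C21orf62 differed by -0.72. TSPAN15L (0.54), the DNA glycosylase MPG (0.51), the histone gene HIST1H2B8 (1.22), PTRHD1 (0.67) and CDHR5 (1.2) were higher at 18 than at 9 g/kg. No gene passed. With limma, 0 genes were called between 9 and 1.8, 18 and 1.8, or 18 and 9 g/kg (lowest adjusted p = 1, 1 and 0.661). The numbers with an unadjusted p below 0.05 were 321, 231 and 645. Without 1.8 g/kg replicate 4 the unadjusted number between 18 and 1.8 g/kg was 397.

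The dose trend and the F test asked for values that follow the dose or differ anywhere. ACKR4, a scavenger receptor for chemokines, had the smallest p among higher slopes, with 5.12 ± 2.47, 4.30 ± 1.95, 7.87 ± 1.31 and 9.00 ± 3.27 TPM from control to 18 g/kg (0.050 ± 0.013 log2 per g/kg). The other higher slopes were those of NFIC (0.021), ACTA1 (0.066), CD55 (0.025) and CMTM8 (0.040 log2 per g/kg). Lower slopes were those of MMP24 (-0.022), TCTA (-0.035), the actin regulator BRK1 (-0.026), GPRC5B (-0.028) and ENKD1 (-0.025 log2 per g/kg). In the F test the smallest p belonged to MBD2, TSPAN15L, the transporter ABCB1LA (33.7 ± 13.4, 59.8 ± 22.8, 32.6 ± 12.2 and 59.9 ± 22.4 TPM), ACKR4 and AGMAT. With limma, 0 genes were called in either test, with lowest adjusted p = 1 for the trend and 0.576 for the F test. The numbers with an unadjusted p below 0.05 were 230 (156 with higher slopes and 74 with lower) and 361. Without 1.8 g/kg replicate 4 the trend had 353.

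The 3 dose comparisons share their control libraries, so similarity between them was set against simulated unchanged groups whose comparisons also shared a control group. The simulated controls were drawn at random from the residuals of all groups, so the real control libraries were not held fixed. Fold differences correlated across genes, with r = 0.539 for 1.8 and 9 g/kg, 0.521 for 1.8 and 18 g/kg and 0.477 for 9 and 18 g/kg. Genes are not independent replicates. Unchanged groups gave means of 0.488, 0.496 and 0.499, and their covariance was as large as the real one in 41, 64 and 47 of 100 simulations. With separate controls, split by odd and even replicate number, r was -0.055 and 0.047, -0.098 and -0.069, and 0.008 and -0.063. No gene was called in both comparisons of any pair (0 genes, and 0 in the simulations). With 0 genes called at each dose this number could only be 0, so it tests nothing.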

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

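The comparison of members adjusted over the list alone with random splits was laid out before its result was seen, and the other tests of patterns and splits in this part were chosen only after the results were seen.

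Interferon response genes were lower than control at all 3 doses, with a mean list difference of -0.34 log2. Without control replicate 7 the mean of the 3 differences was 0.054, so the pattern rests on that library. Its interferon list stood at 7.21 against 3.27 to 4.66 in the other controls, and after rescaling it still stood 3.32 log2 above their mean, which argues against a difference in library scale. The same library had the highest acute phase mean of the controls, and a candidate explanation is an acute infection or immune activation in that sample, for which the design holds no test. Without this library the list was called in the opposite direction at 1.8 g/kg at the preset correlation (0.20 ± 0.32, adjusted p = 0.0246) and was not called at 9 or 18 g/kg. With an estimated correlation and all 3 libraries that stand apart left out, the adjusted p at 1.8 g/kg was 0.865. An effect of arginine on these genes stays open.

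Endothelial markers were higher than control at all 3 doses, by a mean of 0.34 log2, over 15 tested members of which 0 are in another list, STAB1 and LYVE1 among them. Without control replicate 7 the mean difference was 0.18, so whether that library alone makes the pattern cannot be told apart from a smaller difference at each dose. The list was picked among 30 after its difference was seen. The permutation test of 8 control against 24 arginine libraries gave permutation p = 0.00931, and 0.214 adjusted over the 30 lists (0.073 and 0.916 without control replicate 7), so chance is not excluded. In the same test B and plasma cell markers differed by 0.48 (permutation p = 0.0143, 0.214 adjusted). Without control replicate 7 they differed by 0.54 (permutation p = 0.0107, 0.322 adjusted), so chance is not excluded there either. A lower share of hepatocytes should raise other cell types alike. The endothelial minus stellate difference was 0.39 ± 0.17 (SE), but 0.2245 ± 0.15 without control replicate 7, under 2 SE. Markers of B, T, macrophage, heterophil and erythrocyte cells had higher means too (0.17 to 0.48 over the 3 doses), and stellate (-0.06) and cholangiocyte markers (-0.04) did not. A lower hepatocyte share therefore cannot be told apart from a difference in endothelial cells. A higher share or activity of endothelial cells with arginine stays an open hypothesis.

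AGMAT was higher than control at 9 g/kg by 0.78 log2, above the control mean in 8 of 8 libraries, and had higher values at 1.8 and 18 g/kg too. Control replicate 8 stood at 132 TPM, above 9 g/kg replicates 1, 2 and 6 (114, 116 and 99.9 TPM). Control replicates 1 (107 TPM) and 8 had the highest AGMAT of the controls, and they were the 2 controls with HINTW above 1 TPM, against 4 libraries at 9 g/kg. The hepatocyte list itself differed by -0.08 ± 0.08 at 9 g/kg, so relative to it the AGMAT difference was 0.86 ± 0.21 (SE). Hepatocyte markers did not rise with AGMAT. Their list spanned only 0.65 log2 over the 32 libraries, less than the AGMAT difference, so they could hardly have risen as much. No conclusion on hepatocyte share or library scale is drawn from this comparison. With each of the 16 libraries left out in turn the smallest difference was 0.69, which argues against a single library. Its adjusted p over the arginine list alone was 0.0029. Of 100 splits of the 16 libraries, 6 (the real one included) had an adjusted p as low over any of the 30 lists alone, the lowest of the others being 0.000363, so chance is not excluded. More agmatinase transcript with dietary arginine may be a response of arginine disposal through agmatine, a hypothesis found and tested on these data, and the gene did not pass over all genes.

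With limma 0 genes were called in each of the 8 tests, a number that each of the 100 splits per test reaches, so the splits test nothing there. The highest other numbers were 51, 1 and 31 for 1.8, 9 and 18 g/kg against control. They were 1, 1742 and 3 for 9 with 1.8, 18 with 1.8 and 18 with 9 g/kg, 2485 for any difference and 277 for the trend. The median of the other splits was 0 called genes in each of the 8 tests. Whether the splits with many calls reflect a structure of the libraries was not tested. At an unadjusted p below 0.05, 86 of 100 splits had as many genes as the 265 at 1.8 g/kg (highest other 2503), 37 as the 552 at 9 g/kg (1632) and 88 as the 277 at 18 g/kg (2185). Between doses, 55 splits had as many as the 321 for 9 with 1.8 g/kg (2343), 78 as the 231 for 18 with 1.8 g/kg (3876) and 24 as the 645 for 18 with 9 g/kg (2129). For any difference 74 had as many as 361 (4347) and for the trend 80 as many as 230 (2970). Lists called at the preset correlation numbered 12, 7 and 11, and 30, 90 and 42 splits had as many (highest other 20, 16 and 16). Members past the threshold adjusted over the list alone numbered 0, 5 and 0, and 100, 29 and 100 splits had as many (highest other 72, 46 and 78). The 0 members at 1.8 and 18 g/kg are again a number that each split reaches. Chance is not excluded for the unadjusted numbers, the called lists or the 5 members at 9 g/kg.

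Single libraries stood far from the others of their group in 13 of 120 tests of list means and 34 of 416 tests of named genes. About 1 in 20 tests would do so by chance, 6 and 20.8 of them. Control replicate 7 and 1.8 g/kg replicate 4 had the most, 11 and 8. Values are mean log2(TPM + 1) for lists and log2(TPM + 1) for genes.

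Control replicate 7 was high for acute phase genes (8.06), interferon response (7.21), NCOA7 (4.71) and SOCS2 (6.21). It was low for ribosomal proteins (9.47), endothelial markers (2.23), RASGRP3 (0.77), ELOVL6 (5.33), APOB (7.42), LYVE1 (1.91) and the macrophage receptor MRC1 (1.38). The 1.8 g/kg replicate 4 was high for cell cycle genes (4.44), T and NK cells (3.94), B and plasma cells (4.21), macrophages (6.68), JCHAIN (6.25), MKI67 (3.68) and the T cell kinase ZAP70 (2.98), and low for the clock gene CRY1 (4.63). The 9 g/kg replicate 8 was low for fatty acid oxidation (6.23), CPT1A (3.78) and PER3 (0.93). The 9 g/kg replicate 4 was high for heterophil markers (6.69). The 18 g/kg replicate 7 was high for glucose and glycogen genes (8.36), erythrocyte markers (4.36), PLIN2 (7.47) and NDUFC2 (7.58). Control replicate 8 was high for ATF4 response genes (6.05). Control replicate 1 was low for SPIA1 (7.36), ACACA (3.25) and IGF1 (2.00), and control replicate 2 was high for PLAT (3.18) and ACTA1 (2.17). The 1.8 g/kg replicate 3 was low for SPIA1 (7.13) and ACACA (3.06) and high for GATC (5.69). Other 1.8 g/kg libraries were low for FABP1 (9.69, replicate 7) and ABCG5 (2.35, replicate 8) and high for APOC3 (13.90, replicate 1) and DDAH1 (2.61, replicate 2). Other 9 g/kg libraries were low for IGF1 (2.84, replicate 1) and TCTEX1D2 (1.97, replicate 5) and high for ABCG5 (4.92, replicate 2). At 18 g/kg, replicate 1 was low for GHDC (1.92) and GATC (4.80), and replicate 5 was high for HSD17B11 (4.86) and PPIL6 (1.74).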

How the results depend on the processing

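Leaving out the 3 libraries that stand apart (control replicate 7, 1.8 g/kg replicate 4 and 9 g/kg replicate 4) and, for gene lists, leaving out each library in turn were chosen after seeing the data, and the other alternatives were planned. The number of called genes was 0 in each test run under each alternative except 1, and 0 to 0 with each library left out in turn. The minimum difference of 1 log2 could only give 0, since it narrows the genes called without it, which numbered 0. Alternatives covered all 8 tests, apart from the minimum difference and the compared groups alone (6 tests), the dose rank (1) and each library left out (5). With limma and a library left out, 224 to 361 genes had an unadjusted p below 0.05 at 1.8 g/kg, 446 to 910 at 9 g/kg and 208 to 441 at 18 g/kg. With library weights and robust eBayes, 8 genes were called at 9 g/kg (1508 at an unadjusted p below 0.05, with 628 at 1.8 g/kg and 883 at 18 g/kg, where 0 were called). They were MBD2 (0.59), POU2AF1 (0.74), SOCS2 (1.58), TSPAN15L (-0.62), TCTEX1D2 (-0.69), PPIL6 (-1.34), CTIF (-0.79) and LOC417447 (-0.87), with adjusted p from 0.0228 to 0.0308. CTIF and LOC417447 were named after their values were seen. Control replicate 7 had the lowest weight, 0.342. Of 100 splits, each with library weights estimated anew, 7 (the real one included) called as many genes (highest other 154), so chance is not excluded. With the replicate number as a block limma called 0 genes in each test (320, 661 and 338 at an unadjusted p below 0.05 at the 3 doses), and residuals of libraries that share a number did not correlate alike (-0.31 to 0.37). Named genes gave 12032 values on the same side of the threshold, 11755 with the same sign and 277 with the other, from 59 of 463 gene and dose pairs. Another 6 were newly past it and 0 passed in the opposite direction. AGMAT at 9 g/kg ranged from 0.69 to 0.89 (adjusted p 0.084 to 0.998) and MBD2 from 0.54 to 0.67 (0.0228 to 0.954).

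List calls depended on the assumed correlation between genes. With an estimated correlation 0 lists were called at each dose, and 30 of 30 calls ended. After rescaling, 11, 4 and 8 lists were called at 1.8, 9 and 18 g/kg, 8 calls ended and 1 list was newly called. Without the 3 libraries 9, 4 and 8 lists were called at 1.8, 9 and 18 g/kg, 14 calls ended, 5 lists were newly called and 5 reversed. Interferon response then pointed up (adjusted p = 0.00607, 0.307 and 0.853), as did acute phase at 1.8 g/kg (0.0181), while ribosomal proteins pointed down at 18 g/kg (0.00923). With these libraries out and an estimated correlation 0 lists were called at each dose, and interferon response pointed up (0.865, 0.887 and 0.956). Leaving out control replicate 7 alone gave the same 5 turns of the camera direction and 1 more, ribosomal proteins at 9 g/kg (0.0484), so that library accounts for them. The interferon mean at 18 g/kg itself stayed below control (-0.04), and the acute phase mean at 1.8 g/kg was above it before (0.07) and after (0.29). It gave 0.0246, 0.541 and 0.838 for interferon response, 0.0301 for acute phase at 1.8 g/kg and 0.0123 for ribosomal proteins at 18 g/kg. With each library left out in turn, 6 to 14, 2 to 10 and 7 to 12 lists were called at 1.8, 9 and 18 g/kg. Adjusted p then ran from 1.16e-05 to 0.418, 1.3e-05 to 0.541 and 3.93e-10 to 0.838 for interferon response, and from 0.0301 to 0.94 for acute phase at 1.8 g/kg. For ribosomal proteins it ran from 0.00734 to 0.993 at 9 g/kg and from 0.000727 to 0.952 at 18 g/kg. Rescaling also moved the share of higher genes among those with an unadjusted p below 0.05, from 61.9 to 51.7% at 1.8 g/kg, 44.4 to 48.9% at 9 g/kg and 67.9 to 45.9% at 18 g/kg, so that balance is no finding. Without counts, the part of the spread that comes from depth cannot be separated.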

Other observations

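The relations between lists in this part were computed after seeing the data, and HINTW was named after its values were seen.

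Marker lists of some immune cells had wide ranges over the 32 libraries. The heterophil list ran from 1.11 to 6.69 in mean log2(TPM + 1), the highest being 9 g/kg replicate 4 and the next 4.47, and macrophage markers from 3.41 to 6.68. Cell cycle genes ran from 1.42 to 4.44. Hepatocyte markers spanned only 10.0 to 10.7.

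Some list means were correlated across the 32 libraries. All 435 relations between the 30 list means were computed, and 33 had an adjusted permutation p below 0.05. Fatty acid oxidation followed glucose and glycogen metabolism, lists that share 0 genes (Pearson r = 0.776, permutation p = 1e-05, the smallest possible, adjusted p = 0.00218, Spearman rho = 0.554, permutation p = 0.00121). It was 0.664 without the 2 libraries farthest from the median, and 0.742, 0.812, 0.741 and 0.915 within control, 1.8, 9 and 18 g/kg. Nuclear OXPHOS genes ran opposite to hepatocyte markers (r = -0.667, permutation p = 3e-05, adjusted p = 0.00435, rho = -0.667, permutation p = 5e-05). That relation was -0.646 without the 2 farthest libraries, and -0.829, -0.279, -0.833 and -0.933 within the 4 groups, so it was weak at 1.8 g/kg. TPM are shares of a library, which ties abundant hepatocyte transcripts to all others.

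Of the 14 clock genes, 0 had an unadjusted p below 0.05 at 1.8 g/kg, 3 at 9 g/kg and 2 at 18 g/kg. None passed over all genes or adjusted over the list alone (lowest 0.573, 0.0849 and 0.13). TEF was higher at 9 g/kg (0.45 ± 0.15) and CRY1 lower (-0.30 ± 0.13), and at 18 g/kg PER2 was lower (-0.61 ± 0.25) and NPAS2 higher (0.66 ± 0.25). The labels give no time of sampling.

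The labels give no sex. The W-linked transcript HINTW was at 20.1 to 37.7 TPM in 12 libraries and listed at 0 in 20. Of the 8 libraries per diet, 2 in control, 3 at 1.8 g/kg, 4 at 9 g/kg and 3 at 18 g/kg had it above 1 TPM. With the mean of 62 W-linked genes as a covariate limma called 0 genes in each of the 8 tests, with 293, 529 and 294 genes at an unadjusted p below 0.05 at 1.8, 9 and 18 g/kg.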
